A study of Mus musculus with 6 samples.

How the data were processed

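Bulk RNA from mouse prefrontal cortex was measured in 6 libraries, 3 injected with AAV9 carrying GFP and 3 with AAV9 carrying a short hairpin RNA against Kmt5b. Groups and replicate numbers came from the sample titles. Per the labels' protocols, stranded total RNA libraries were made after removal of ribosomal RNA and sequenced on an Illumina HiSeq instrument, and reads were trimmed with Cutadapt and aligned to RefSeq mRNAs with TopHat2. Per the submitters' processing notes, STAR, featureCounts, DESeq2 and the build mm10 were used. The protocol and the notes thus name different aligners, and neither says which libraries each applied to. The labels give the mice as C57BL6/J, while the design text gives a cross with C3H. The design text counts 2 control mice and the labels 3 control libraries, so a pair of GFP libraries could come from 1 mouse. P-values then measure only the spread between these libraries.

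The deposited values are raw read counts per gene symbol, with 54429 rows per library. Even values outnumbered odd ones among low counts, as where both mates of a read pair are counted. The GFP libraries had 2504, 2698 and 2742 genes at 2 counts, and the Kmt5b shRNA libraries 2288, 2290 and 2356. At 1 count they had 910, 890 and 833 against 1109, 1048 and 1033. At 3 counts they had 511, 554 and 558 against 644, 660 and 681. This pattern was thus stronger in every GFP library, and the reason was not tested. Standard errors come from a fit that takes in the spread between libraries as well as counting error, and that draws on the spread of other genes. Replicates of a group differed by far more than sampling noise, with a chi-square per gene of 18.2 to 45.0. All 37 mitochondrial rows were 0 in every library, so the mitochondrially encoded genes were not analysed here. There were 26 date-like symbols, as left by a spreadsheet, and 53825 rows matched a symbol of GENCODE M21. Total counts ranged from 29490771 to 74723284.

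Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, scaled by TMM, and tested by the robust quasi-likelihood fit with legacy=TRUE, with Benjamini-Hochberg adjusted p under 0.05. SE is the absolute log2 fold change divided by the square root of F. CPM values use TMM library sizes, and the values of genes sharing no sequence use the library sizes of that fit. Intervals use 95% confidence and the residual degrees of freedom. Of 34 gene lists, 32 were tested with camera in limma 3.58.1 at a preset correlation of 0.01, each with at least 5 tested members. The sex-linked list was left out of these tests. Y-linked Ddx3y lay between 84.9 and 112.8 CPM and Xist at or below 0.572 CPM in all 6 libraries, so the groups did not differ in sex.

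The groups, the main test, the gene lists, the rule for named genes and the alternatives listed last were fixed before the data were examined. The rule took Kmt5b, Kmt5a and Kmt5c, then the 10 called genes of largest change in each direction with non-overlapping CPM and average log2 CPM of at least 1, up to 2 tested members of smallest p of each list per direction and the 5 genes of smallest p per direction. Unnamed gene models were passed over. The rule was applied again to genes sharing no sequence. Igkc, Jchain, Mbp and the lymphocyte genes of the closing section were chosen after their values were seen.

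Shared sequence was found by aligning GENCODE M21 transcripts to each other with BLAST+ 2.17.0 at 90% identity over at least 100 nucleotides. A copy was an intronless gene covered over at least 50% of its length by a gene with introns, its parent. There were 5166 such copies of 1824 parents. Protein-coding genes termed genes sharing no sequence were fitted alone. They had no match of 200 nucleotides, or of 50% of a gene's length, to another protein-coding gene or to a pseudogene. Shorter matches, and matches to other noncoding genes, were allowed. In another fit the counts of copies were added to parents. A further fit took protein-coding genes only. These fits were chosen after the data were seen. The genome itself was not searched, so copies outside the annotation were not used here.

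The alternatives were DESeq2 1.42.0, other scalings, filters and tests, a fit with the replicate number as a block, each library left out in turn, and a fit without 393 mitochondrial and ribosomal RNA rows. Gm26917 and Gm42418, which overlap ribosomal RNA, were added by hand to those rows. The tests were checked on simulated counts with 200 changed genes and a list of 40 more raised by 0.5 on the log2 scale. The simulations held no opposite shifts of copies and parents, so their rates may not carry over to the real fit of all genes. For Kmt5b shRNA against GFP over 24419 genes, edgeR recovered 84% of 100 genes changed by 1 and 36% of 100 changed by 0.5 on the log2 scale, and 9.33% of its calls were false. Over the 12692 genes sharing no sequence it recovered 89% and 52%, with 6.82% false. DESeq2 gave 21.4% and 12.4% false calls in these simulations.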

Results

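Prefrontal cortex from mice aged 6 to 8 weeks was profiled by bulk sequencing of ribosome-depleted total RNA. The cortex had been injected with AAV9, an adeno-associated virus used to deliver genes to neurons, that carried either green fluorescent protein (GFP) or a short hairpin RNA against Kmt5b. Kmt5b is a histone methyltransferase of lysine 20 of histone H4 and is linked to autism. The labels gave 3 GFP control libraries and 3 Kmt5b shRNA libraries, while the design text counted 2 GFP control mice. The GFP libraries held 69869079, 29490771 and 74723284 counts, and the Kmt5b shRNA libraries 57486203, 48828638 and 54254006. No two-sided exact permutation test on 3 against 3 libraries can give a p below 0.1. The comparison asked which transcripts differ in prefrontal cortex when Kmt5b is targeted. The series title links it to synaptic function, DNA repair and transcription.

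Kmt5b, on chromosome 19 from 3767421 to 3818303 (mm10), was not clearly lower in the libraries labelled Kmt5b shRNA. Its counts were 5784, 2451 and 6333 in the GFP libraries and 3900, 3730 and 3507 in the Kmt5b shRNA libraries. This was 82.4 ± 3.59 CPM (counts scaled to library size; SD, n = 3) against 70.9 ± 8.42 CPM (SD, n = 3), a log2 fold change of -0.22 ± 0.10 (SE). The edgeR quasi-likelihood adjusted p was 0.303 and the two-sided exact permutation p was 0.2. The estimated change was -14.0%, with a 95% interval from -29.5% to 5.03%. The adjusted p takes in all 24419 genes tested, which is strict for a single gene named in advance. In the fit of genes sharing no sequence, the Kmt5b log2 fold change was -0.23 ± 0.09 (SE, edgeR adjusted p = 0.265). The library labelled Kmt5b shRNA replicate 2, at 80.3 CPM, lay within the GFP range of 79.7 to 86.5 CPM, so every direction below rests on the labels. Kmt5a, which places the first methyl group on the same lysine and shares sequence with copies, was higher at 44.1 ± 4.6 CPM in the Kmt5b shRNA against 32.8 ± 2.69 CPM in the GFP libraries (SD, n = 3 each), a log2 fold change of 0.43 ± 0.11 with an edgeR adjusted p of 0.0192. The Kmt5a adjusted p was 0.0638 without GFP replicate 2, 0.0939 without GFP replicate 3, 0.0756 without Kmt5b shRNA replicate 1 and 0.0875 without Kmt5b shRNA replicate 3. It was 0.0622 after counts of Kmt5a copies were added to the gene. Kmt5c, the related methyltransferase, had a log2 fold change of -0.16 ± 0.21 and an adjusted p of 0.805.

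Over all genes, 60 of 78 cytosolic ribosomal protein genes were higher in the Kmt5b shRNA libraries, as were 299 of 1478 spliced genes that have intronless copies, and 995 of 1731 such copies were lower. Protein-coding genes sharing no sequence had a median log2 fold change of 0.00, against 0.11 for the spliced parents of copies. Of 24419 genes tested, 676 were higher and 1390 lower at an edgeR adjusted p under 0.05. Intronless copies of spliced genes made up 71.6% of the lower calls, with 39 higher and a median log2 fold change of -1.65. The spliced parents of such copies made up 44.2% of the higher calls, with 10 lower. Copies of genes that have no introns themselves were lower in 17 of 85 cases, and unprocessed pseudogenes with a parent in 10 of 62. Copies of spliced genes took 1.24%, 1.24% and 1.2% of counts in the GFP libraries and 0.254%, 0.260% and 0.258% in the Kmt5b shRNA libraries. Their parents took 11%, 10.8% and 10.5% against 12.3%, 12.8% and 12.2%.

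**Figure D1:**
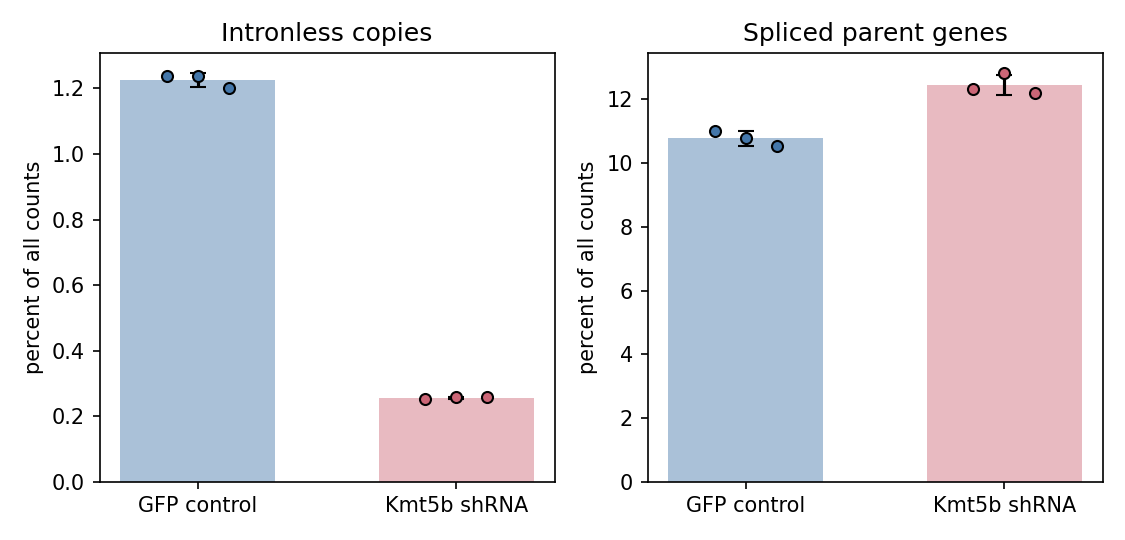
Percent of all counts (vertical axes, from 0) on intronless copies of spliced genes (left) and on their spliced parent genes (right). Bars are group means, error bars SD and points the 3 libraries of each group; the copies lie at 1.2% or above in every GFP library and at 0.260% or below in every Kmt5b shRNA library.

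The ribosomal protein gene Rps29 had 2.29 ± 0.470 CPM in the GFP libraries and 191.5 ± 3.11 CPM in the Kmt5b shRNA libraries (SD, n = 3 each), a log2 fold change of 6.35 ± 0.14 with an edgeR adjusted p of 1.93e-13. With the counts of its copies added, Rps29 had 175.8 ± 11.2 CPM in the GFP against 193.5 ± 2.80 CPM in the Kmt5b shRNA libraries, a log2 fold change of 0.14 ± 0.09 and an adjusted p of 0.616. Not every parent moved this far when copies were added: Rps23 went from a log2 fold change of 5.45 ± 0.11 to 4.82 ± 0.11, and Ppia, which encodes the peptidyl-prolyl isomerase cyclophilin A, from 5.0 to 1.38 ± 0.13. The pseudogene Oaz1-ps had 82.2 ± 8.86 CPM in the GFP libraries and 0.341 ± 0.131 CPM in the Kmt5b shRNA libraries, a log2 fold change of -7.88 ± 0.19. The other genes of largest change or smallest p by the naming rule were Rps27, Rpl17, Rpl38, Rpl31, Rpl12, Rpl21-ps15 and the small RNA genes Rnu1a1 and Rnu3b4 upward. Downward they were Rps25-ps1, Rpl19-ps11, Rpl7-ps7, Fabp3-ps1, Ftl1-ps1, Rps15-ps2, Rps24-ps3, Mrpl23-ps1, Mrip-ps, Rps6-ps4 and the immunoglobulin segment Ighv1-26. Ribosomal protein genes, pseudogenes, small RNA genes and immunoglobulin segments have near-identical relatives, so their individual values are uncertain. Adding copies to parents changed the median log2 fold change of the 299 higher parents from 0.94 to 0.34, and 109 of them still passed. That fit called 301 genes higher and 317 lower.

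Among cytosolic ribosomal protein genes, 60 of 78 were higher and 0 lower over all genes tested, and 63 were higher adjusted over the list alone. Their median log2 fold change was 1.48 (camera adjusted p = 1.51e-210, and adjusted p = 0.0591 with an estimated correlation). With copies added the median was 0.44, with 41 members higher and 4 lower.

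**Figure D2:**
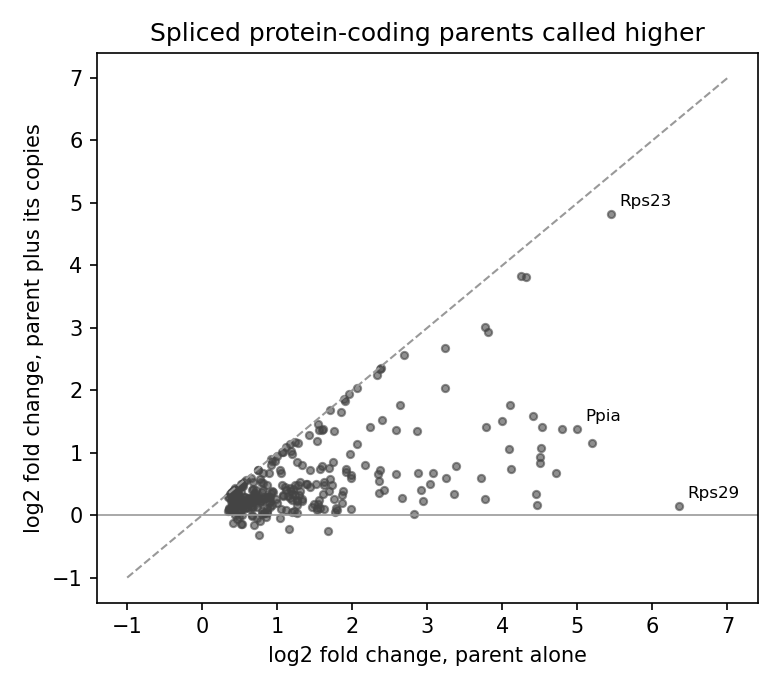
Log2 fold change (Kmt5b shRNA over GFP) of spliced protein-coding parents called higher, counted alone (horizontal axis) and with the counts of their intronless copies added (vertical axis). Each point is a gene, the dashed line marks equal values, and Rps29 moves from 6.35 to 0.14 while Rps23 stays near the line, from 5.45 to 4.82.

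Because of this split, genes sharing no sequence were also fitted alone, a choice made after the data were seen. If the groups were processed differently, that fit need not remove the difference, since counts of genes without copies could also move. Its calls therefore cannot be told apart from such a difference. In that fit Fabp7, a brain fatty acid binding protein of astrocytes and neural progenitors, was higher in every Kmt5b shRNA library, at 68.4 ± 4.75 CPM against 26.8 ± 3.06 CPM in the GFP libraries (SD, n = 3 each). CPM pairs of genes sharing no sequence below give the Kmt5b shRNA libraries first. Its log2 fold change was 1.35 ± 0.10 with an edgeR adjusted p of 0.000223. Cxadr, a cell adhesion protein and virus receptor, was higher by 0.88 ± 0.09 on the log2 scale, the lipase Lpl by 0.97 ± 0.13, the peptide Grp by 1.01 ± 0.14 and angiotensinogen Agt by 1.05 ± 0.17. Wnt10b, a secreted Wnt ligand, was higher at 3.59 ± 0.244 against 0.724 ± 0.193 CPM. Gpr179, Kcne1l, Onecut2, Mdga1 and Hbegf completed the higher genes named by size, with log2 fold changes of 2.36, 2.20, 1.19, 1.16 and 1.11. The sodium channel subunit Scn4b was lower at 58.4 ± 4.14 against 91.5 ± 6.53 CPM, a log2 fold change of -0.65 ± 0.09 with an edgeR adjusted p of 0.0166. The Scn4b adjusted p was 0.0621 without GFP replicate 3, 0.111 without Kmt5b shRNA replicate 1 and 0.0521 without Kmt5b shRNA replicate 3. In the fit of all genes it was at most 0.00612 with any library left out. The Scn4b SE with all libraries was nevertheless larger there, 0.104 against 0.0894. Benjamini-Hochberg adjustment is less strict where many genes pass, as copies and their parents do in that fit. Passing in the fit of all genes, here and below, is thus not further evidence for a gene.

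Downward, the naming rule by size gave the chemokine Cxcl13 (-2.54 ± 0.38) and the T cell co-receptor Cd4 (-1.66 ± 0.25) first among the genes sharing no sequence. The complement inhibitor Serping1 (-1.35 ± 0.24) and Fam221b (-1.33 ± 0.23) came next. The Serping1 edgeR adjusted p was 0.0499, and its log2 fold change was -0.97 without GFP replicate 3. Serping1 passed in 1 of the 6 fits with a library left out, as did Hbegf, whose edgeR adjusted p was 0.0428. Naaa, Csrnp1, Sdc4, Pbxip1 and the astrocyte water channel Aqp4 followed at -0.85, -0.77, -0.73, -0.68 and -0.65.

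Of 12692 genes sharing no sequence, 51 were higher and 27 lower, and all 78 also passed in the fit of all genes. The ribosomal protein gene Rpl41, of a class whose values are uncertain, was among them. It was higher by 0.68 ± 0.10 (edgeR adjusted p = 0.0188). Leaving out 1 library gave 117 higher and 107 lower without GFP replicate 1, 8 and 3 without GFP replicate 2, and 4 and 1 without GFP replicate 3. It gave 2 and 1 without Kmt5b shRNA replicate 1, 51 and 11 without replicate 2, and 11 and 5 without replicate 3. Of 27 called genes picked from this fit by the naming rule, 26 still passed without GFP replicate 1, 6 without GFP replicate 2, 4 without GFP replicate 3, and 2, 19 and 11 without Kmt5b shRNA replicates 1, 2 and 3. Fabp7 and Cxadr passed in all 6 of these fits, with adjusted p up to 0.00368 and 0.0265. In the fit of all genes, 26 of the 27 passed with any library left out, and Scn3b had an adjusted p of 0.0531 without Kmt5b shRNA replicate 1. DESeq2 called 287 higher and 201 lower.

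**Figure D3:**
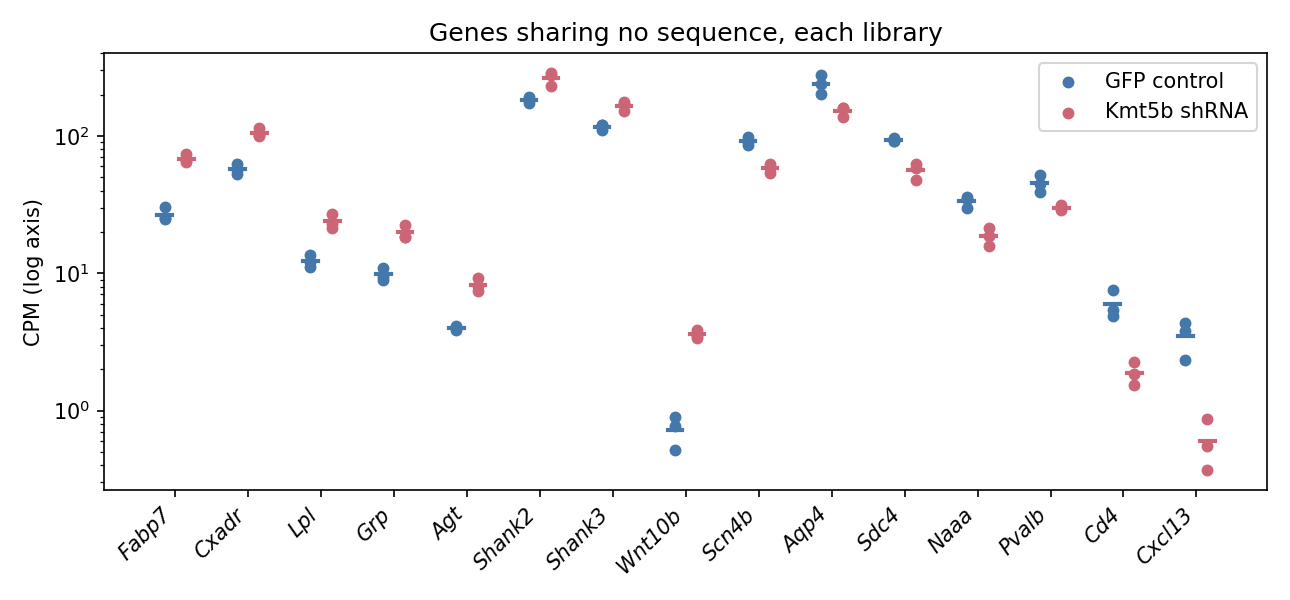
CPM on a log axis for 15 genes sharing no sequence, chosen from those the report names; points are the 3 libraries of each group and short lines their means. Fabp7 lies at 64.7 CPM or above in the Kmt5b shRNA libraries and at 30.3 CPM or below in the GFP libraries.

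Postsynaptic density scaffold genes, which anchor receptors at excitatory synapses, were shifted upward as a list, while in the same fit astrocyte markers had a median log2 fold change of -0.22, oligodendrocyte markers -0.41 and oligodendrocyte precursor markers 0.11. List calls at the preset correlation carry a limit that holds for every list below: the real groups gave 8 called lists in the genes sharing no sequence, other splits that mix both groups gave up to 14, and with an estimated correlation 0 lists passed. In the genes sharing no sequence 2 of 29 members passed, Shank3 and Shank2, and 4 were higher adjusted over the list alone. Shank3 was at 165.9 ± 13.2 against 116.6 ± 5.87 CPM (log2 fold change 0.51 ± 0.09, edgeR adjusted p = 0.0296). Shank2 was at 265.7 ± 29.7 against 182.8 ± 8.49 CPM (0.54 ± 0.09, edgeR adjusted p = 0.0343). Without GFP replicate 2, GFP replicate 3, Kmt5b shRNA replicate 1 or Kmt5b shRNA replicate 3 in turn, the adjusted p was 0.0856, 0.0957, 0.176 and 0.0804 for Shank3 and 0.0945, 0.114, 0.186 and 0.0861 for Shank2. In the fit of all genes both passed with any library left out, with adjusted p up to 0.0239 and 0.0229. The list median was 0.19 (camera adjusted p = 3.28e-05, and adjusted p = 0.472 with an estimated correlation). Glutamate receptor genes had a median of 0.13 with 0 of 28 members called (camera adjusted p = 0.00341, and adjusted p = 0.405 with an estimated correlation), and over all genes the list was not called (camera adjusted p = 0.132). Ubiquitin enzymes had a median of 0.09 with 0 of 36 called (camera adjusted p = 0.0159, and adjusted p = 0.835 with an estimated correlation). Their median was 0.05 without Kmt5b shRNA replicate 2 (camera adjusted p = 0.354) and 0.06 without GFP replicate 2 (adjusted p = 0.0607), and their adjusted p was 0.0807 without GFP replicate 3.

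DNA repair lists did not pass. Double-strand break repair genes had a median log2 fold change of -0.08 with 0 of 30 members called (camera adjusted p = 0.242), and Chek2 had -0.73 ± 0.30 (edgeR adjusted p = 0.289). Tdg, a repair glycosylase that shares sequence with copies, was higher in the fit of all genes by 0.92, and by 0.81 with copies added (edgeR adjusted p = 0.000249). Pcna, the replication and repair clamp, was higher by 0.48 in the fit of all genes, but had 0.16 with copies added (adjusted p = 0.664), and its adjusted p was 0.0598 without GFP replicate 2 and 0.0623 without Kmt5b shRNA replicate 2. Excision and mismatch repair genes had a median of -0.03 with 0 of 28 called (camera adjusted p = 0.928). Targets of p53 had a median of 0.11 with 0 of 30 called (camera adjusted p = 0.187). Among them Eda2r had 1.34 ± 0.28 (edgeR adjusted p = 0.0577) and the cell cycle inhibitor Cdkn1a 0.63 ± 0.18 (edgeR adjusted p = 0.135). In the fit of all genes both passed, Eda2r with an adjusted p of 0.00236 and Cdkn1a with 0.0331. The adjusted p of Cdkn1a there was 0.0762 without GFP replicate 1, 0.121 without GFP replicate 3, 0.0769 without Kmt5b shRNA replicate 1 and 0.111 without Kmt5b shRNA replicate 3. The heat shock list was called higher over all genes with 7 of 27 members higher (camera adjusted p = 0.0452). With copies added, 4 of 27 were higher and the list stayed called (camera adjusted p = 0.0213, and adjusted p = 0.926 with an estimated correlation). In genes sharing no sequence, which keep 16 of its members, its median was -0.01 with 0 called. The respiratory chain list was called higher over all genes (camera adjusted p = 0.00531) although its median was -0.02 and its mean 0.20, and in genes sharing no sequence its median was -0.10 with 0 of 37 called. Over all genes, the camera adjusted p with an estimated correlation was 0.937 for heat shock and 0.956 for the respiratory chain.

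Type I interferon response genes were higher as a list among the genes sharing no sequence, with 20 of 22 members above 0, a median of 0.53 and 10 of 22 higher adjusted over the list alone, although 0 passed adjusted over the 12692 genes of that fit (camera adjusted p = 6.75e-08, and adjusted p = 0.835 with an estimated correlation). Rsad2, an antiviral interferon-induced protein, was at 43.8 ± 19.5 against 10.7 ± 1.60 CPM (SD, n = 3 each, edgeR adjusted p = 0.0577), and the chemokine Cxcl10 at 16.3 ± 4.71 against 9.31 ± 1.42 CPM (SD, n = 3 each, edgeR adjusted p = 0.0905). In the fit of all genes 3 of 35 members passed, Rsad2, Cxcl10 and Oasl2, with edgeR adjusted p of 0.0285, 0.0123 and 0.0218. They passed in 2, 3 and 4 of the 6 fits with a library left out, and their highest adjusted p was 0.124 without GFP replicate 3, 0.0737 without Kmt5b shRNA replicate 3 and 0.110 without GFP replicate 3. Without Kmt5b shRNA replicate 3, the list median was 0.21 (camera adjusted p = 0.000205), and in the fit of all genes it was 0.17 in place of 0.50, with a camera adjusted p of 0.0832 in place of 0.00531.

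Over all genes, the astrocyte, oligodendrocyte and oligodendrocyte precursor lists were not called (camera adjusted p = 0.428, 0.316 and 0.307). Astrocyte and oligodendrocyte markers were lower as lists in the genes sharing no sequence. Astrocyte markers had a median log2 fold change of -0.22, with Aqp4 the called member of 22 and 7 lower adjusted over the list alone (camera adjusted p = 3.02e-05, and adjusted p = 0.405 with an estimated correlation). Oligodendrocyte and myelin markers had a median of -0.41 with 1 of 23 members above 0 and 0 called, and 1, Olig2, higher adjusted over the list alone (camera adjusted p = 0.000243, and adjusted p = 0.835 with an estimated correlation). The oligodendrocyte median was -0.16 without Kmt5b shRNA replicate 1 (camera adjusted p = 0.0548), -0.30 without GFP replicate 1 (adjusted p = 0.0587) and -0.64 without Kmt5b shRNA replicate 3 (adjusted p = 6.93e-12). Mbp, the myelin basic protein, had 1227 ± 424.7 CPM in the Kmt5b shRNA and 1630 ± 303.2 CPM in the GFP libraries (SD, n = 3 each, edgeR adjusted p = 0.542), and ranged from 772 to 1613 CPM within the Kmt5b shRNA libraries. Oligodendrocyte precursor markers had a median of 0.11 with 0 of 18 called (camera adjusted p = 0.0400, and adjusted p = 0.835 with an estimated correlation). The precursor list had an adjusted p of 0.0587 without GFP replicate 1, 0.0807 without GFP replicate 3, 0.413 without Kmt5b shRNA replicate 3, where its median was 0.07, and 0.0556 over genes with CPM of at least 1. Pvalb, which marks a class of inhibitory interneurons, was lower, with a log2 fold change of -0.58 ± 0.11, and was the called member of 21 interneuron markers. Pvalb, Fcrls and Aqp4 passed in 1 of the 6 fits with a library left out, that without GFP replicate 1, and their highest adjusted p was 0.195, 0.156 and 0.153, each without Kmt5b shRNA replicate 1. In the fit of all genes these genes passed in all 6, with adjusted p up to 0.0302, 0.0156 and 0.0128. The microglial gene Fcrls was higher by 0.63 ± 0.11 and was the called member of 22 microglia markers. Blood cell markers had a median of -0.86 with 0 of 10 members above 0, and Cd4 was the called member (camera adjusted p = 1.19e-05, and adjusted p = 0.405 with an estimated correlation). The blood list leaves out the haemoglobin genes there, as they share sequence; in the fit of all genes it was not called, with 4 of 15 members above 0 and a median of -0.68 that turned to 0.11 over genes with CPM of at least 1 (camera adjusted p = 0.886). Its median among genes sharing no sequence was -1.64 without Kmt5b shRNA replicate 1 and -1.81 without replicate 3. Excitatory neuron, endothelial, meningeal, choroid plexus, striatal and olfactory marker lists were not called in the genes sharing no sequence, and Scn4b was the called member of 17 striatal markers.

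Of 54 immunoglobulin gene segments tested over all genes, 11 were lower in the Kmt5b shRNA libraries and 0 higher, with a median log2 fold change of -5.13 over all segments. The 11 are 20.4% of the segments, and 5.69% of all genes tested were lower; the segments were not tested as a group. Igkc, the kappa light chain constant region, had 74.6, 792.2 and 341.5 CPM in the GFP libraries and 15.4, 2.75 and 6.34 CPM in the Kmt5b shRNA libraries, and its adjusted p was 0.112. The immunoglobulin J chain gene Jchain, which shares no sequence, had 5.04 ± 3.12 CPM in the Kmt5b shRNA and 123.4 ± 75.2 CPM in the GFP libraries (SD, n = 3 each) and an edgeR adjusted p of 0.130.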

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

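The fits without shared sequence, with copies summed and with protein-coding genes only were chosen after the data were seen, as were all alternatives, those for gene lists included, run on genes sharing no sequence. Counts over all genes, 676 higher and 1390 lower, ran from 467 to 965 and from 979 to 1928 under other tools, scalings and filters and with 1 library left out. They fell to 51 and 27 with genes sharing sequence left out, where 12692 genes were tested, and to 301 and 317 with copies summed into parents, and the lower count was 184 with protein-coding genes only. Among genes sharing no sequence, the 51 higher and 27 lower became 287 and 201 with DESeq2, 94 and 64 with no low-count filter and 142 and 70 with limma-voom quality weights. Leaving out 1 library gave 2 to 117 higher and 1 to 107 lower. The direction of all 78 called genes held in each of these settings, and the cause of the changed counts was not tested. The Kmt5b log2 fold change ran from -0.31 without Kmt5b shRNA replicate 2 to -0.14 without Kmt5b shRNA replicate 3 and passed in no setting.

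Replicate numbers did not pair the samples: same-number deviations correlated at 0.03, -0.08 and 0.26. With a replicate block, 704 genes were higher and 1507 lower over all genes, and 90 and 90 among genes sharing no sequence.

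The 6 lists called higher became 0 with an estimated correlation, 1 with fry, 10 on limma-voom values, 3 with CPM of at least 1 and 3 with protein-coding genes only. Leaving out 1 library gave 2 to 8. With genes sharing sequence left out, an estimated correlation again gave 0. The 0 lists called lower became 2 on limma-voom values, 3 with genes sharing sequence left out, 3 with copies summed, 2 with protein-coding genes only and 0 to 1 with 1 library left out. With genes sharing sequence left out, the heat shock list turned to a median of -0.0102 and the respiratory chain list to -0.1029, each also with an estimated correlation. Too few blood markers sharing no sequence had CPM of at least 1 for a list test. Named genes kept direction and call in 4296 gene settings, lost the call in 238 and gained it in 180, counting as kept 17 values that changed sign without being called in either fit.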

Other observations

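The counts over other splits, and the channel genes in the fit of all genes, followed rules fixed before the data were examined. All other tests in this part were chosen after the results were seen. The splits of genes sharing no sequence use a set of genes chosen after the data were seen. Among voltage-gated channels sharing no sequence, Scn3b was higher by 0.41 ± 0.08 and Scn4b was lower at -0.65 ± 0.09, and the other 31 of 33 members were not called. Scn3b passed in 1 and Scn4b in 3 of the 6 fits with a library left out, with edgeR adjusted p up to 0.191 and 0.111, each without Kmt5b shRNA replicate 1. In the fit of all genes they passed in 5 and 6, and Scn1a, which shares sequence, was lower at -0.60 ± 0.11 (edgeR adjusted p = 0.00188) and passed in all 6. The brain-specific small RNA Bc1 had 3491, 660.1 and 3562 CPM in the GFP libraries and 266.4, 122.5 and 201.8 CPM in the Kmt5b shRNA libraries, with an edgeR adjusted p of 0.102.

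Of the spliced parents of intronless copies, 299 of 1478 were higher in the Kmt5b shRNA libraries, and 995 of 1731 copies were lower. A change in transcription of the parents argues for copies at or above 0, but the copies of parents called higher had a median log2 fold change of -1.52, and a change in the copies alone leaves unexplained that 96.8% of called parents were higher. Depth is argued against, since the Kmt5b shRNA depths lie between those of the GFP libraries while the highest share of counts on copies in a Kmt5b shRNA library was 0.260%. A candidate explanation is that reads across splice junctions were placed on intronless copies when the GFP libraries were processed: 57.5% of copies of spliced genes were lower against 20% of copies of intronless genes (Fisher's exact p = 6.49e-12). This p takes copies as independent, although copies of the same parent share sequence, and does not measure the spread between libraries. Reads across splice junctions do not account for lower copies of intronless genes or for unprocessed pseudogenes, lower in 16.1%, against 1.28% of protein-coding genes sharing no sequence. Nor do annotated copies account for parents such as Rps23, at 4.82 with copies added. Which of the aligners named was used for which library is not given in the sources used here. It is therefore not known whether the groups were processed differently, and such a difference could not be told apart from the treatment.

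Of 54 immunoglobulin segments 11 were lower in the Kmt5b shRNA libraries, while Igkc and Jchain did not pass. Residual blood is argued against by a median log2 fold change of 0.18 over 5 erythrocyte genes in the fit of all genes. The haemoglobin genes among them share sequence, so their individual values are uncertain. Alas2, which is not a haemoglobin gene, had -0.16 ± 0.20 (SE, edgeR adjusted p = 0.786). Reads shared between immunoglobulin segments and more lymphocytes in the GFP tissue, whether from the vector, the animals or Kmt5b, cannot be told apart: of the lymphocyte markers in the blood list that share no sequence, 1 had a mean log2 CPM of at least 1, Cd4 at -1.66. Of 26 lymphocyte markers sharing no sequence, picked after values were seen, 24 lay below 0 with a median of -1.34 and 2 were called (Cd4 and Blk), but 15 had a mean log2 CPM under 1. The most abundant were Xbp1, which cortex also expresses, at -0.07 ± 0.08, and Jchain at -4.59 ± 0.88, and 6 of the 30 listed markers are also in the blood list.

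Kmt5b in the library labelled Kmt5b shRNA replicate 2 resembled the GFP libraries. The lowest GFP library had 79.7 CPM against 66.2 ± 3.25 CPM (SD) in the other 2 Kmt5b shRNA libraries. The Kmt5b values cannot decide on a swap with a GFP library, since Kmt5b was not clearly lower in the Kmt5b shRNA group. Copies of spliced genes took 0.260% of counts in replicate 2, and 0.254% and 0.258% in Kmt5b shRNA replicates 1 and 3. They took 1.24%, 1.24% and 1.2% in the GFP libraries, which argues against a swap of labels after the counts were made. An earlier swap is not covered, since that share may come from the processing. Weak knockdown in the animal of replicate 2, or few infected cells in the dissected tissue, may account for its Kmt5b level and was not tested.

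Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 2066 genes and 78 genes sharing no sequence, and the highest other split called 0 in each. The real split was the only 1 to reach those counts. Every other split mixes both groups, so any difference between the groups widens its spread and lowers its calls. These counts thus do not tell a difference in processing from the treatment. For gene lists the real split called 6 over all genes and the highest other 18, with all 10 splits reaching 6. Among genes sharing no sequence it called 8 lists, the highest other 14, and 7 splits reached 8. Camera calls at the preset correlation were thus as frequent for groupings that mix both treatments.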
